A study of Homo sapiens with 6 samples.

How the data were processed

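Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HEK293T cells, a line derived from human embryonic kidney that carries the SV40 large T antigen. The series held 6 libraries. A pair of antibodies recognised the histone variant H2A.Z, from CST and from Abcam, and the resulting lists are called H2AZ CST and H2AZ Abcam here. The other antibodies recognised the variant H3.3, acetylated lysine 16 of histone H4 (H4K16ac) and dimethylated lysine 79 of histone H3 (H3K79me2), with 1 library each. The last library was input chromatin, of which no values were used here. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min and the chromatin was sheared by sonication. Per the same protocols, each library started from 10 ng of DNA, went through 13 amplification cycles and was selected for fragments of 250 to 450 bp.

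Peaks were the starting point. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0 were used, and coordinates refer to the human build hg38. The settings of these tools, the handling of duplicate reads and of reads that match several places, and the way the input library entered peak calling are not given in the sources used here. Each peak list was called from a single library, and read depth per library is not given in the sources used here. The deposited lists hold, for each peak, its position and summit, and the authors' fold enrichment at the summit, a linear ratio. They also hold the authors' −log10 p-value and −log10 q-value and an integer score that the authors' caller derived for display. The fold and the −log10 q are the authors' values and were used only to describe, rank or filter peaks within a list. The score column was not used. The smallest −log10 q lay between 2.00 and 2.06 in the 5 lists, and no peaks of a list overlapped each other.

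Peaks on chromosomes 1 to 22 and X were analysed. Genes came from a RefSeq table of assembly GRCh38.p14, the same assembly as hg38. It gives a chromosome, a start and an end for each gene but neither strand, exons nor untranslated regions, and no genome sequence was used here. The analysis was planned before the data were examined, and several planned steps were adapted to this table. Windows planned around transcription start sites became windows of 1 kb around either end of the 19451 protein-coding genes of at least 1 kb, so a window can also catch the end of a gene or a neighbouring gene. Random placement planned outside assembly gaps became placement between the first and last gene or peak of each chromosome. It left out 33 stretches of at least 1 Mb with no annotated gene of at least 1 kb and no peak. The placement span was 2851 Mb. Classes of exon, intron and untranslated region were not assigned. A planned rule on peaks from 5 kb upstream of a gene was applied to 5 kb on both sides. Genes were oriented by H2AZ. This was possible for the 11722 genes with H2AZ in both antibodies' lists at the same end and in neither list at the other end. Of these, the 9501 of at least 10 kb were used for position along genes.

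For each pair of lists, the number of peaks of the first list overlapped by at least 1 bp was divided by its mean over 100 random placements on the same chromosome, and the log2 of this ratio is reported. Intervals are 95% percentile intervals from 1000 bootstrap draws of 5 Mb genome blocks, and a log2 ratio was called when its interval excluded 0. The same was done for summits within 1 kb of a gene end. Per gene, log2 odds ratios of a peak of each list at either end were computed over the 19451 genes. They were computed again within genes that carried both other lists and within genes that lacked both. Each antibody has 1 library, so there is no replicate spread and no p-value. The intervals cover variation between regions of the genome within these libraries only. Exact Clopper-Pearson intervals at 95% are given for shares, and they cover counting error only. A total of 26 gene lists were fixed before the data were examined. For each, the share of members with a peak at an end and the median share of the gene covered were set against 10000 random lists of the same size matched on gene length in 10 classes. Percentiles among these random lists describe these libraries only. The random genes were drawn independently of their position, whereas members of clustered families can share peaks. For such families the percentiles can overstate how unusual a list is.

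Named genes follow a rule fixed in advance. They are the 5 genes with the highest −log10 q at an end for H2AZ CST, H3.3 and H4K16ac, and the 5 genes with the longest part covered by H3K79me2. For 7 pairs of lists, each way, they are the 3 genes with the strongest peak of the first list and none of the other within 5 kb of the gene. They are also up to 2 members of each gene list with the highest summed −log10 q, up to 2 members with no peak at an end, and every gene of the list of variant and mark machinery. Some genes that the rule takes are not named in the text. Genes named outside this rule are marked as chosen after their values were seen.

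Alternatives were peaks of −log10 q of at least 5, the 10000 strongest peaks of each list, a 50% overlap, summit overlap, peaks within 1 kb joined, and peaks moved by 100 kb to 1 Mb. Others were autosomes only, gene-end windows of 500 bp and of 2 kb, and all 43067 annotated genes of at least 1 kb. Chosen after seeing the data were a placement of gene-end peaks at other gene ends, leaving out the distal 3 Mb of each chromosome, leaving out peaks near the featureless stretches, and no minimum gene length.

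The overlap statistic was tested on simulated data made from the 52325 H2AZ CST peaks set against the H3.3 list. With no planted overlap it called 0 of 20 simulated lists. With planted log2 ratios of 1.38, 2.84 and 3.95 it returned means of 1.38, 2.83 and 3.93. The unplanted lists were built with the same random placement as the expected counts, so they check the calculation only. They do not measure false calls for lists that share a preference for gene ends or chromosome ends. The odds ratio over 19451 genes called 2 of 20 simulations with no association. It returned means of 1.01 and 3.02 for planted log2 values of 1 and 3, calling all 20 of each. These simulations drew genes independently, with no correlation along chromosomes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.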

Results

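Peak lists from 5 antibodies were compared in unperturbed HEK293T cells: H2AZ CST and H2AZ Abcam for the variant H2A.Z, and 1 list each for the variant H3.3, H4K16ac and H3K79me2. H2A.Z and H3.3 are histone variants found in nucleosomes at the starts of active genes. H3.3 is also deposited in transcribed genes and at telomeric repeats. H4K16ac is the acetylation written by KAT8, and H3K79me2 is written by DOT1L within transcribed genes. The study's title and the labels place these libraries beside mass spectrometry of whole nucleosomes. The question put to the data was where in the genome each variant lay together with each mark. Each antibody had 1 library and therefore no replicates. Intervals on log2 ratios and log2 odds ratios cover variation between genome regions, intervals on shares cover counting error, and neither covers variation between cultures or libraries.

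H3.3 and H4K16ac gave the longest lists, and H3K79me2 covered the most sequence. On chromosomes 1 to 22 and X there were 52325 H2AZ CST peaks, 44634 H2AZ Abcam peaks, 72287 H3.3 peaks, 76748 H4K16ac peaks and 54476 H3K79me2 peaks. They covered 20.9, 23, 30.8, 29.2 and 64.2 Mb in the same order. Median peak widths lay between 287 bp for H4K16ac and 496 bp for H3K79me2. The H3K79me2 list held peaks of up to 65794 bp, and 56.6% of its covered bases lay in peaks wider than 2 kb. Total read counts per library are not given in the sources used here, so a longer list does not show that a mark was more widespread.

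In the full lists H2AZ was the signal most concentrated at gene ends, and over 50% of the H3.3, H4K16ac and H3K79me2 summits lay elsewhere inside genes. Summits fell within 1 kb of an end of a protein-coding gene for 39.1% of H2AZ CST peaks, 42.2% of H2AZ Abcam peaks, 27.9% of H3.3 peaks, 20.3% of H4K16ac peaks and 20% of H3K79me2 peaks. These windows made up 2.5% of the placement span. Against random placement the log2 ratios were 3.63 (95% interval 3.50 to 3.78) for H2AZ CST, 3.73 (3.59 to 3.90) for H2AZ Abcam, 2.95 (2.72 to 3.22) for H3.3, 2.58 (2.41 to 2.78) for H4K16ac and 2.71 (2.60 to 2.85) for H3K79me2. Elsewhere inside protein-coding genes lay 75.8% of H3K79me2 peaks, 59.4% of H4K16ac peaks, 52.3% of H3.3 peaks and 28.5% of H2AZ CST peaks. Protein-coding genes with their end windows made up 45.3% of the placement span. Only 1.76% of H3K79me2 peaks lay outside all annotated genes of at least 1 kb, against 23.9% of H2AZ CST peaks. With the 10000 strongest peaks of each list, 65.8% of H3K79me2 and 50.9% of H3.3 summits lay at gene ends, against 67.6% for H2AZ CST, and the log2 ratio of H3K79me2 there was 4.36. With peaks moved by 100 kb to 1 Mb that of H4K16ac was 1.76.

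The antibodies to H2AZ marked largely the same places, and the peaks they did not share were mostly weak ones. Of the H2AZ CST peaks, 72.6% overlapped an H2AZ Abcam peak, against 1.76% of randomly placed peaks (log2 5.36, 5.23 to 5.51). In the other direction the share was 74.8%, and 56.8% of all bases covered by either list were covered by both. By quartile of −log10 q, from lowest to highest, 35.5%, 60.8%, 94.2% and 99.98% of H2AZ CST peaks overlapped an H2AZ Abcam peak. The 14355 peaks found with the CST antibody alone lay near a gene end in 11.7% of cases, against 49.5% for shared peaks. H3.3 peaks overlapped 21.6% of the former and 64.5% of the latter. The 11232 peaks of the Abcam antibody alone lay near a gene end in 25.1% of cases. Genes with a CST peak at an end and no Abcam peak within 5 kb numbered 212. The strongest of them were FAM156A on chromosome X, CYB5B, which encodes a cytochrome b5 of the mitochondrial outer membrane, and the chemokine gene CCL26. The reverse held for 266 genes, led by SALL3, a zinc finger factor of the spalt family, RMI2, a subunit of the BLM helicase complex, and the potassium channel gene KCNQ3. With gene-end peaks placed at other gene ends, a placement chosen after seeing the data, the log2 ratio of the antibodies was 2.60.

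Along genes, H2AZ formed a narrow block at a single end, H3K79me2 spread from that end into the gene, and H3.3 and H4K16ac rose again towards the far end. These profiles covered the 9501 genes of at least 10 kb among the 11722 oriented by their H2AZ. In the first 500 bp inside the H2AZ end, peaks covered 62.1% of bases for H2AZ CST, 72.8% for H2AZ Abcam, 41.9% for H3.3, 25% for H4K16ac and 64.5% for H3K79me2. From the first to the second 10% of the 9501 genes of at least 10 kb, coverage by H2AZ CST fell from 15.0% to 1.09%. H3K79me2 went from 45.6% in the first 10% to 24.4% in the next and 1.5% in the last. H3.3 had its minimum of 2.66% in the third 10% segment and reached 5.28% in the last, and H4K16ac went from 2.15% in the second to 5.46% in the last. At the far end, 15.0% of genes had an H3.3 peak within 1 kb, against 9.97% in a mid-gene window of the same width, a difference of 5.05 percentage points (4.02 to 6.14). For H4K16ac the difference was 4.02 points (2.90 to 5.16), and for H3K79me2 it was −9.01 points (−9.75 to −8.28). At 4773 genes no other annotated gene of at least 1 kb lay within 5 kb of the far end. There the difference was 2.20 points (1.36 to 3.09) for H3.3 and 2.22 points (1.24 to 3.32) for H4K16ac. Because H2AZ set the orientation, its own asymmetry here follows from the choice of genes.

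**Figure D1:**
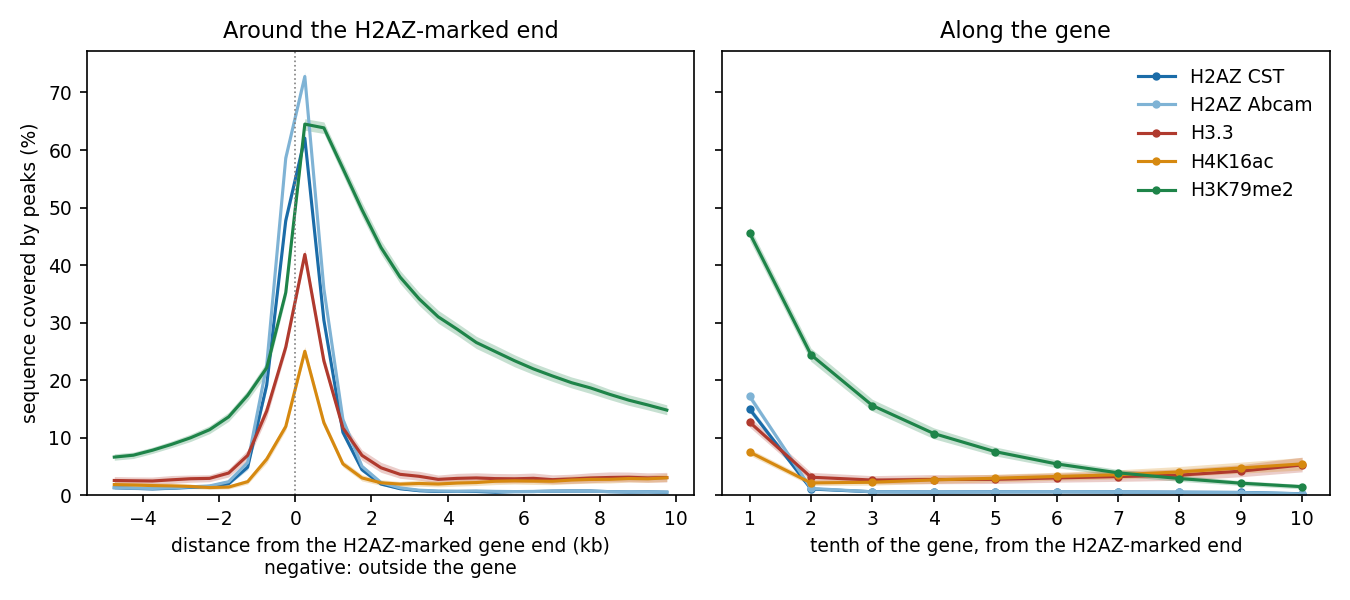
Percent of bases covered by peaks of each list in the 9501 oriented genes of at least 10 kb. Bins of 500 bp run from 5 kb outside to 10 kb inside the H2AZ-marked end, and 10% segments run across the gene. Shading is the 95% block-bootstrap interval. H3K79me2 falls from 45.6% to 1.5% across the gene, while H3.3 ends at 5.28% and H4K16ac at 5.46%.

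H3.3 peaks overlapped every other list more often than random placement gave. Of 72287 H3.3 peaks, 60.6% overlapped an H4K16ac peak, against 3.56% when placed at random (log2 4.09, 3.85 to 4.36). H2AZ CST peaks overlapped 38.6% of them (log2 4.16, 3.90 to 4.45) and H2AZ Abcam peaks 40.0% (log2 4.26, 4.0 to 4.56). H3K79me2 peaks overlapped 34.8% (log2 3.07, 2.91 to 3.27). Among H3.3 peaks the log2 ratio for H4K16ac exceeded that for H3K79me2 by 1.02 (0.91 to 1.13). The order of the shares differed with the 10000 strongest peaks of each list, where H3.3 peaks overlapped H3K79me2 in 46.6%, H2AZ CST in 36.4%, H2AZ Abcam in 43.1% and H4K16ac in 26.2% of cases. The log2 excess of H4K16ac over H3K79me2 was 0.41 with those peaks, 1.56 with a 50% overlap and 0.41 with peaks moved by 100 kb to 1 Mb. From the lowest to the highest quartile of −log10 q of H3.3, the share with H4K16ac went from 47.3% to 76.1%, and the share with H3K79me2 from 19.3% to 59.5%.

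H2AZ peaks overlapped H4K16ac and H3K79me2 more often than random placement gave. H4K16ac peaks overlapped 42.3% of H2AZ CST peaks (log2 3.91, 3.74 to 4.10) and 46.6% of H2AZ Abcam peaks (log2 3.93, 3.76 to 4.13). H3K79me2 peaks overlapped 32.8% of H2AZ CST peaks (log2 3.18, 3.06 to 3.33) and 35.2% of H2AZ Abcam peaks (log2 3.24, 3.11 to 3.38). With the 10000 strongest peaks of each list the shares of H2AZ CST were 18.5% with H4K16ac and 44.8% with H3K79me2. Those of H2AZ Abcam were 20.7% and 47.3%, the reverse order. The log2 ratios of these peaks kept their order, at 4.70 and 4.51 for H2AZ CST and 4.73 and 4.57 for H2AZ Abcam. When placed at random, 0.71% of these H2AZ CST peaks overlapped H4K16ac and 1.97% overlapped H3K79me2. Each mark was also asked which variant lay with it. H3.3 overlapped 58.8% of H4K16ac peaks and H2AZ CST overlapped 29.9%. Against random placement this favoured H3.3 by a log2 of 0.18 (0.06 to 0.31), which was −0.41 with peaks moved by 100 kb to 1 Mb and 0.01 with equal numbers of peaks. For H3K79me2 peaks, H3.3 overlapped 33.6% and H2AZ CST 23.6%, and the difference of log2 ratios was 0.00 (−0.09 to 0.10). The interval of that difference reached 0, and with peaks moved by 100 kb to 1 Mb it was −0.33. H3K79me2 peaks of higher −log10 q overlapped the variants more often. In the highest quartile 78.8% overlapped H3.3 and 70.5% H2AZ CST, against 11.4% and 3.49% in the lowest. The quartiles had no random placement and were not matched on peak width, and wider peaks meet other peaks more easily. With at least 50% of the peak covered, the shares of all H3K79me2 peaks were 19.1% for H3.3 and 10.5% for H2AZ CST.

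H4K16ac and H3K79me2 had the lowest overlap ratio of all pairs. Of the H4K16ac peaks, 25.2% overlapped an H3K79me2 peak, against 3.91% when placed at random (log2 2.69, 2.58 to 2.83). With gene-end peaks placed at other gene ends the log2 ratios of the 10 pairs of lists lay between 1.53 for H2AZ Abcam with H3K79me2 and 3.01 for H3.3 with H4K16ac. With peaks moved by 100 kb to 1 Mb they lay between 1.46 for H4K16ac with H3K79me2 and 4.49 for the antibodies to H2AZ.

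**Figure D2:**
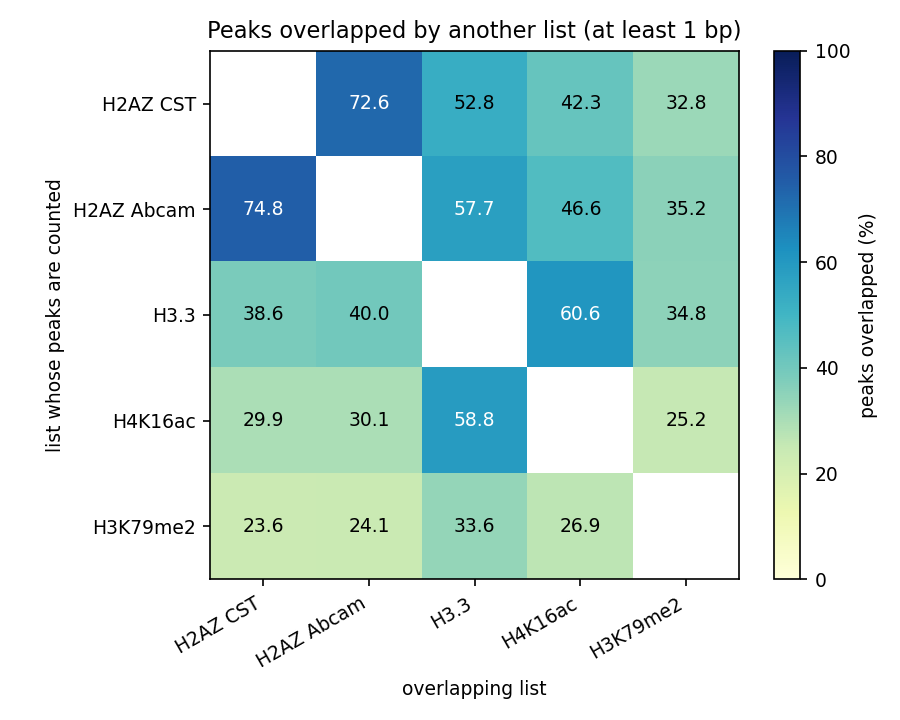
Percent of peaks of each list (rows) overlapped by at least 1 bp by peaks of each other list (columns), with the share printed in each cell. The largest shares join the antibodies to H2AZ, at 72.6% and 74.8%, and H3.3 with H4K16ac, at 60.6%.

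Most protein-coding genes carried either all of the signals at an end or none of them. Of 19451 genes, 7462 (38.4%) had H2AZ CST, H3.3, H4K16ac and H3K79me2 at their ends, and 4389 (22.6%) had none. A further 1986 genes lacked only H4K16ac, 1666 lacked only H3K79me2, and 752 had H2AZ CST alone. H2AZ CST lay at an end of 70.7% of genes (70.1 to 71.4, exact binomial), H2AZ Abcam at 71.1% (70.4 to 71.7), H3.3 at 64.5% (63.8 to 65.2), H4K16ac at 55% (54.3 to 55.7) and H3K79me2 at 55.4% (54.7 to 56.1). Of the genes with H3.3, 28.4% had it at both ends, and of those with H2AZ CST 9.45% did. At least 50% of the gene was covered by H3K79me2 in 1452 genes, by H3.3 in 693 genes, by H4K16ac in 366 genes and by H2AZ CST in 68 genes. With the 10000 strongest peaks of each list the share of genes with H4K16ac was 16.3%.

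H3K79me2 went with H2AZ, and H3.3 went with every other list, whereas H4K16ac and H3K79me2 were only weakly associated among genes alike in the variants. Genes with H2AZ CST carried H3K79me2 in 75.6% of cases and other genes in 6.49% (log2 odds ratio 5.48, 5.29 to 5.72). Within the genes that carried H3.3 and H4K16ac it was 3.80 (3.49 to 4.15), and within those that lacked both it was 4.95 (4.60 to 5.32). H3.3 and H2AZ CST had a log2 odds ratio of 4.99 (4.83 to 5.17), which was 1.39 (0.42 to 2.12) within the 7900 genes that carried the marks and 4.34 (3.99 to 4.71) within the 5882 that lacked them. For H3.3 and H4K16ac it was 4.44 (4.27 to 4.60), with 3.22 (2.96 to 3.47) where H2AZ CST and H3K79me2 were present and 5.34 (4.99 to 5.74) where both were absent. For H3.3 and H3K79me2 it was 4.15 (4.02 to 4.29), with 2.56 (2.31 to 2.80) where H2AZ CST and H4K16ac were present and 4.02 (3.46 to 4.58) where both were absent. For H2AZ CST and H4K16ac it was 3.64 (3.50 to 3.79), with 0.98 (0.54 to 1.43) where H3.3 and H3K79me2 were present and 2.80 (2.54 to 3.07) where both were absent. H4K16ac and H3K79me2 had 2.53 (2.41 to 2.65), which was 0.38 (0.21 to 0.53) within the 11690 genes with both variants and 0.71 (−0.30 to 1.40) within the 4834 genes with neither. With the 10000 strongest peaks of each list the log2 odds ratios were 2.41 for H2AZ CST and H3K79me2, 2.23 for H3.3 and H2AZ CST, 2.55 for H3.3 and H4K16ac, 2.75 for H3.3 and H3K79me2, 1.62 for H2AZ CST and H4K16ac and 2.03 for H4K16ac and H3K79me2. Over all annotated genes they lay between 3.59 for H4K16ac and H3K79me2 and 5.87 for H2AZ CST and H3K79me2.

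H2AZ CST was strongest at the end shared by ELP2, a subunit of Elongator, and SLC39A6, a zinc transporter (chromosome 18, ELP2 from 36129899 to 36180557), with a −log10 q of 218 in that list. ZNF557 followed at 215, the secreted ligand gene WNT3A at 214 and KIAA0319L, the receptor for adeno-associated virus, at 200. The H3.3 list was led by DHPS, which takes part in making the hypusine residue of a translation factor (chromosome 19, 12672470 to 12681880), at 246. Next came a single peak at 220 near the ends of MYL11, SEPTIN1 and ZNF48 on chromosome 16, and the kinase gene PKN2 at 216. H4K16ac was strongest at the end shared by CHTOP, an mRNA export factor, and S100A13, at 135. It was followed by ZNF274 at 127, SRCAP, which encodes the ATPase that deposits H2A.Z, at 121, and TASOR, the scaffold of the HUSH silencing complex, at 114. The longest H3K79me2 coverage lay in ANKRD11 (chromosome 16, 89267630 to 89490561), a chromatin regulator, with 85.9% of the gene covered, and LOC128462377, annotated inside it, with 94.8%. KANSL1, the scaffold of a KAT8 complex, was covered over 55.5% although no list had a peak at its annotated ends. FAM193A was covered over 40.5%.

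Genes with a strong peak of one list and none of another named the exceptions. FOXC1, HOXC9 and HOXA10, transcription factors of development, led the 164 genes with H3K79me2 at an end and no H2AZ CST within 5 kb, with −log10 q of 879, 766 and 751 in the H3K79me2 list and 100% of each gene covered. H3.3 without H2AZ CST was found at 291 genes, led by the histone gene H2BC5 at 202 in the H3.3 list, the tubulin gene TUBA1B at 109 and HOXA5 at 86.3. The lack of H2AZ here refers to the CST list alone. H2AZ Abcam had a peak at an end of H2BC5 and another inside HOXA10. The reverse, H2AZ CST without H3.3, was found at 1380 genes, led by KIF14, a kinesin of cell division, PIGC, which acts in the synthesis of membrane anchors, and SAMD12. KIF14 and PIGC carried H3K79me2. H3.3 without H4K16ac was found at 1701 genes, led by H2BC5, RABIF and THUMPD3, and H4K16ac without H3.3 at 555, led by PIGC, C11orf16 and ZNF619. H3.3 without H3K79me2 was found at 2169 genes, led by the T cell antigen gene CD7, the neuronal gene APLP1 and RAP1GAP2. H3.3 peaks covered 100% of CD7. H3K79me2 without H3.3 was found at 714 genes, led by TMEM126A, MKI67, the proliferation marker Ki-67, and NET1. WNT3A, ENPP7, an intestinal sphingomyelinase, and the kinase gene IKBKE led the 2181 genes with H4K16ac and no H3K79me2. In the reverse, 1902 genes were led by TMEM126A, HOXA4 and GAPVD1. H2AZ CST lacked H4K16ac at 2561 genes, led by ZNF557 and the neighbours SWT1 and TRMT1L, and lacked H3K79me2 at 2688, led by WNT3A, ANKRD35 and SPOCD1. H4K16ac without H2AZ CST was found at 357 genes, led by TNFRSF6B, PTPRCAP and LOC107984876. These counts rest on each list's calling threshold, and TNFRSF6B and PTPRCAP are small genes whose windows take in neighbouring genes.

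H3K79me2 lay at an end in over 85% of the members of each gene list of this paragraph, apart from MYC and the immediate early genes. Ribosomal protein genes had it at an end in 82 of 83 cases, against a median of 47.0% in random lists of matched length, and the median member was covered over 74.4%. H3.3 lay at 79 of these 83, H2AZ CST at 75, H2AZ Abcam at 75 and H4K16ac at 62. RPL35 and RPL10A had the strongest signals, with −log10 q of 869 and 783 for H3K79me2, and RPL26L1 had no end peak. Splicing factors had H3K79me2 at 41 of 42 genes, with SRSF2 covered over 100% and HNRNPD over 94.2%, and H3.3 at 37, H2AZ CST at 38, H2AZ Abcam at 40 and H4K16ac at 25. Translation factors had H3K79me2 at 34 of 35, H2AZ CST at 33, H2AZ Abcam at 32, H3.3 at 29 and H4K16ac at 25, led by EIF4E and EEF1D. U2AF1 and EIF3C were the members without an end peak in those groups, and each has a near-identical copy in this assembly. The handling of reads that match several places is not given in the sources used here. The other groups with H3K79me2 above every matched random list or nearly so were proteasome (34 of 39), complex I (34 of 36), heat shock (18 of 19), cell cycle (39 of 40), RNA polymerase III (23 of 25), DNA repair (31 of 35) and chromatin remodeller genes (37 of 39). H2AZ CST lay at 37, 34, 16, 39, 25, 34 and 36 of them in that order, and H2AZ Abcam at 35, 35, 16, 39, 23, 34 and 34. H3.3 lay at 29, 31, 17, 37, 20, 28 and 36, and H4K16ac at 24, 23, 17, 35, 21, 26 and 29. H4K16ac was above 99.5% of random lists for ribosomal protein genes, heat shock genes such as HSPD1 and HSPE1 and cell cycle genes such as CDT1 and CDC25A. The same held for polymerase III factors such as GTF3C4 and SNAPC4. It also held for the remodeller list, which includes the histone methyltransferase genes KMT2B and KMT2D. H4K16ac was near the random median for splicing factors, at percentile 60.6, and for proteasome genes such as PSMD12 and PSMC5, at 73.9. MYC and the immediate early genes had H2AZ CST at 18 of 20, H2AZ Abcam at 19, H3.3 at 18, H4K16ac at 13 and H3K79me2 at 16. JUN and FOSL1 led them, and H2AZ CST covered 16.2% of the median member against 2.60% in random lists.

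The HOX clusters encode factors that pattern the body axis. H3K79me2 and H3.3 peaks covered a larger part of each cluster than H2AZ and H4K16ac peaks did. All 39 HOX genes of at least 1 kb had an H3.3 peak at an end and 36 had H3K79me2, while H4K16ac lay at 22, H2AZ Abcam at 21 and H2AZ CST at 18. H2AZ CST stood at percentile 5.70 of the random lists, H2AZ Abcam at 26.6 and H3.3 at 100. Genes of a cluster can share peaks, which the random lists did not reproduce, so these percentiles can overstate how unusual the family was. The HOXA cluster (chromosome 7, 27092993 to 27200091) was covered over 92.3% by H3K79me2, 32.9% by H3.3 in 72 peaks, 3.27% by H4K16ac, 2.39% by H2AZ CST and 3.66% by H2AZ Abcam. Coverage by H3K79me2 was 65.3% in HOXC, 42.3% in HOXB and 36.7% in HOXD, and coverage by H3.3 was 25.2%, 16.6% and 20.5%. H2AZ CST covered 4.66%, 3.93% and 6.52% of them and H2AZ Abcam 6.60%, 4.13% and 8.54%, against 0.734% and 0.806% of the placement span. HOXC10 and HOXB7 had the strongest summed signal, and H3K79me2 covered 100% of each.

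**Figure D3:**
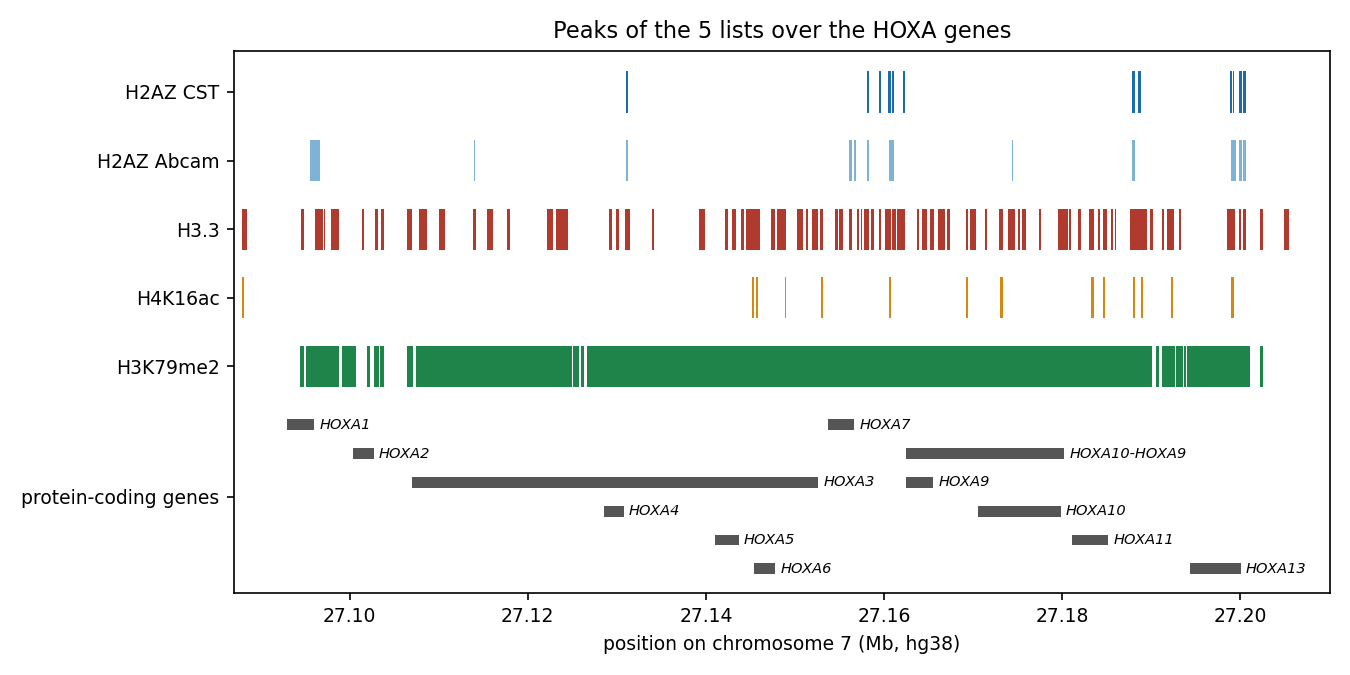
Map of the HOXA cluster on chromosome 7 (hg38, position in Mb) with the annotated genes and the peaks of each list as boxes. H3K79me2 covers 92.3% of the span, H3.3 32.9% in 72 peaks, and H2AZ CST 2.39% in 11 peaks.

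Of 65 developmental transcription factor genes, 52 had H2AZ CST, 50 H2AZ Abcam, 56 H3.3, 47 H4K16ac and 35 H3K79me2, the last at percentile 72.6 of the random lists. H3.3 covered 19.3% of the median member against 1.67% in random lists, H3K79me2 14.8% against 0.382%, H2AZ CST 9.36% against 1.60% and H4K16ac 6.39% against 0.925%. FOXC1 and DLX2 were covered over 100% by H3K79me2, while IRX2 and OTX2 had no end peak. Of 21 renal developmental factors, 18 had H2AZ CST, 16 H2AZ Abcam, 17 H3.3, 15 H4K16ac and 8 H3K79me2, the last at percentile 4.34. H3K79me2 covered 0.946% of the median member against 2.08% in random lists, and 55.6% of SALL1. Pluripotency genes had few peaks: H2AZ CST at 7 of 19, H2AZ Abcam at 6, H3.3 at 9, H4K16ac at 6 and H3K79me2 at 1, which was SOX2, covered over 78.5%. SALL4 had H2AZ and H3.3, whereas CRIPTO and DPPA2 had no end peak.

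Markers of differentiated tissues, kidney among them, mostly lacked H3K79me2, and some of these groups also had few of the other signals. H3K79me2 lay at 1 of 24 kidney markers (LRP2, the tubular endocytic receptor), 1 of 25 immune markers (CD68), 1 of 21 muscle markers, 2 of 20 liver markers (TF and APOA1) and 8 of 30 neuronal markers, each at percentile 0.06 or lower. For muscle the gene was TTN, which encodes titin and was chosen after its values were seen. H4K16ac lay at 15 of the kidney, 10 of the immune, 11 of the muscle, 2 of the liver and 8 of the neuronal markers. H2AZ CST lay at 13, 12, 12, 5 and 22 of them, H2AZ Abcam at 9, 12, 6, 4 and 24, and H3.3 at 12, 11, 7, 4 and 19. Liver markers stood at percentile 0.02 or lower for every list, H4K16ac at neuronal markers at 0.1, and H2AZ Abcam at 0.02 for kidney and 0.025 for muscle markers, where H2AZ CST stood at 3.21 and 17.6. SCNN1A, a subunit of the epithelial sodium channel, had H2AZ, H3.3 and H4K16ac without H3K79me2. SYT1, a synaptic vesicle protein gene, had H2AZ and H3.3, and so did the muscle gene MYOD1, with H2AZ CST over 71.7% of it and H3.3 over 73.1%. CKM, CD4 and NCAM1 also had H2AZ. Among liver genes H2AZ lay at TF, APOA1, APOC3, SERPINA1 and TAT, H3.3 at all of these but SERPINA1, and H4K16ac at APOA1 and APOC3. APOC3, SERPINA1 and TAT were chosen after their values were seen. No end peak was found at CUBN, KCNJ1, CD3G, CD8B, MYF6, MYH1, AFP, AHSG, DCX or GAD1.

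Large gene families differed widely in how many of their members had peaks at an end. Among 241 olfactory receptor genes H2AZ CST lay at 8, H2AZ Abcam at 7, H4K16ac at 3, H3.3 at 2 and H3K79me2 at 0. OR1F1 and OR2V2 were the strongest and made up the H3.3 count, and OR10C1, chosen after its values were seen, was the other gene with H4K16ac. OR10A2 and OR10A3 had no end peak. Among 55 keratin genes the counts were 12, 10, 18, 5 and 2 in the order H2AZ CST, H2AZ Abcam, H4K16ac, H3.3 and H3K79me2. KRT18 and its partner KRT8, keratins of simple epithelia, were the genes with H3K79me2, and H3.3 lay at KRT86, KRT18, KRT13, KRT19 and KRT9. Of these, KRT8, KRT13, KRT19 and KRT9 were chosen after their values were seen. KRT86 had the strongest H2AZ, and KRT1 and KRT10 of the epidermis had no end peak. Clustered protocadherin genes, which give neurons their surface identity, had H2AZ CST at 11 of 53, H2AZ Abcam at 14, H3.3 at 23, H4K16ac at 2 and H3K79me2 at 0. PCDHGA11 and PCDHGC4 were the strongest, PCDHAC2 and PCDHGC3, chosen after their values were seen, had the H4K16ac, and PCDHA10 and PCDHA12 had no end peak. The 22 genes of the gamma cluster end together, so their H3.3 count rests on 2 peaks, and the beta cluster had no peak of any list. The 508 zinc finger genes went the other way: H2AZ CST lay at 395, H2AZ Abcam at 397 and H3K79me2 at 333, above 99.4% of random lists, while H3.3 lay at 297, at percentile 0.015, and H4K16ac at 268, at percentile 4.04. The random lists did not reproduce neighbouring members of a family, so these percentiles too can overstate how unusual it was. ZNF786 and ZNF512B carried all 5 signals, and ZNF112 and ZNF117 had no end peak.

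Most genes that make, place and modify these histones had each signal at an end. Of 40 such genes, 39 had H3K79me2, 38 H3.3, 37 H2AZ CST, 37 H2AZ Abcam and 34 H4K16ac, each at percentile 99.86 or higher. H3K79me2 covered 28.9% of the median member against 1.42% in random lists, but H2AZ CST covered 0.889% against 0.926%. SRCAP and H3-3A, a gene for H3.3 itself, had the strongest summed signal, with −log10 q of 179 and 185 for H3.3. H3-3B, the other gene for H3.3, had H3.3 at 47.1 and H3K79me2 at 644 but no H2AZ peak of either antibody. DOT1L, the methyltransferase for H3K79, was covered over 67.3% by H3K79me2, 49.1% by H3.3 and 43.3% by H4K16ac. KAT5, an acetyltransferase of the complex that also exchanges H2A.Z, had H2AZ CST at 196. KAT8, the acetyltransferase for H4K16, had no H2AZ CST peak, and its partner MSL2 was covered over 96.2% by H3K79me2. The deacetylase gene SIRT1 and the H3.3 chaperone genes DAXX and ASF1A lacked H4K16ac, as did MSL3. VPS72, which encodes the H2A.Z chaperone YL1, lacked H3.3 and H4K16ac. The replication-dependent histone genes of at least 1 kb had H3K79me2 at 8 of 8, H3.3 at 5, H2AZ Abcam at 5, H2AZ CST at 3 and H4K16ac at 0. With no minimum length, a setting chosen after seeing the data, the counts of 69 were 34, 46, 30, 23 and 13. H2BC5 and H2BC4 led in H3.3, at 202 and 112, and the other genes with H3.3, chosen after their values were seen, were H2BC12, H2BC21 and H3C4. H2AZ Abcam lay at the same genes and H2AZ CST at H2BC4, H2BC21 and H3C4.

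H3.3 and H4K16ac peaks crowded the ends of chromosomes. Distance was taken from the ends of each chromosome's placement span, and some of these may not be ends of chromosome arms. The distal 3 Mb of the chromosomes held 26.7% (26.4 to 27.1) of H3.3 peaks and 28.2% (27.8 to 28.5) of H4K16ac peaks. They held 13.4% of H2AZ CST peaks, 14.6% of H2AZ Abcam peaks, 12.9% of H3K79me2 peaks and 9.53% of protein-coding genes. Between 1 and 2 Mb from the end there were 196 H3.3 peaks and 214 H4K16ac peaks per Mb, against 14.1 and 14.4 beyond 20 Mb. In the distal 3 Mb 72.3% of H3.3 peaks overlapped H4K16ac, against 56.4% elsewhere. No random placement was made for the distal part alone, where denser H4K16ac peaks also make random overlap more frequent. With the distal 3 Mb left out the log2 ratio of H3.3 with H4K16ac was 4.45, against 4.09 for all peaks. Chromosome 19 held 11.5% of H3.3 peaks and 7.39% of protein-coding genes. There were 9.83 H4K16ac peaks per protein-coding gene on chromosome 22 and 1.36 on chromosome X, and for H3.3 the values were 7.86 and 1.57. H2AZ CST, at 4.22 and 1.54, and H3K79me2, at 3.87 and 1.53, differed in the same direction. Copy number of HEK293T chromosomes, which differs between chromosomes in this line, was not measured here.

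**Figure D4:**
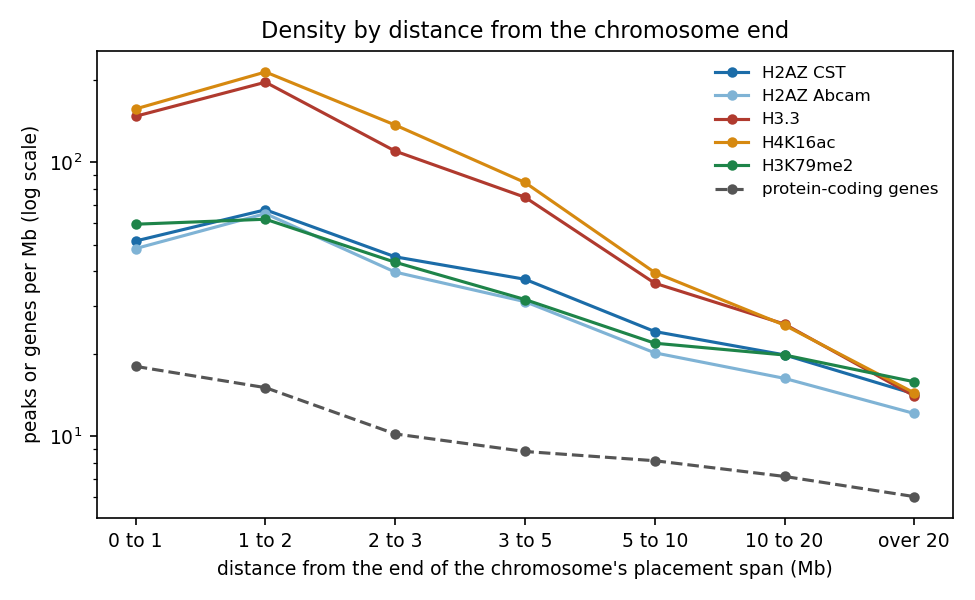
Peaks per Mb of each list and protein-coding genes per Mb, on a log axis, against distance in Mb from the nearer end of the placed span of the chromosome. H3.3 and H4K16ac reach 196 and 214 peaks per Mb between 1 and 2 Mb and fall to 14.1 and 14.4 beyond 20 Mb.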

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

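Tests chosen only after the result was seen were those of gene density, of the strongest peaks, of H3K79me2 in the last part of genes and of the antibodies' own peaks. The tests of a pile-up shared by all libraries at chromosome ends, of neighbouring genes and of distal crowding at far gene ends were written down before. The design gives no group to set against these patterns, so no biological explanation was tested.

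H3.3 and H4K16ac peaks crowded the distal 3 Mb of chromosomes, which held 26.7% and 28.2% of them. Gene density does not account for all of it. Distal 1 Mb bins held on average 125 H3.3 peaks, 141 H4K16ac peaks and 12.1 genes. Other bins held 18.1, 18.7 and 6.08. Set against other bins with the same number of genes, distal bins held 3.09 times (2.61 to 3.66) as many H3.3 peaks. For H4K16ac peaks the ratio was 3.63 (3.06 to 4.29). Long lists of weak peaks do not either: among the 10000 strongest peaks the distal share of H4K16ac exceeded that of H3K79me2 by 21.05 percentage points (14.7 to 26.7). A pile-up common to all libraries stays open. It was predicted to put most distal peaks shared by H3.3 and H4K16ac in each other list. In the H2AZ CST list lay 24.6% (23.1 to 26.6) of them. Elsewhere in the genome the share in that list was 46.8%, also short of most, so the shortfall cannot single out distal regions. Base composition, which is known to be GC-rich near human chromosome ends and could bias 2 of the libraries more than the rest, stays open because no genome sequence was used here.

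H3.3 and H4K16ac peaks also lay at the gene end without H2AZ more often than at mid-gene. Starts of neighbouring annotated genes of at least 1 kb do not account for all of it. Where no other such gene lay within 5 kb of the far end, the excess for H3.3 was 2.20 points (1.36 to 3.09). For H4K16ac it was 2.22 points (1.24 to 3.32), and for all genes the values were 5.05 and 4.02. The excess was not confined to genes of the distal 3 Mb. Without the distal 3 Mb the excess was 4.70 points (3.64 to 5.83) for H3.3 and 3.83 points (2.82 to 4.99) for H4K16ac. This says little about crowding as a cause, since both windows lie in the same gene and a crowded region raises both. Crowding also reached past the cut, with 74.6 H3.3 peaks per Mb between 3 and 5 Mb against 14.1 beyond 20 Mb. A pile-up at gene ends common to all libraries stays open: H3K79me2 coverage changed by −0.61 points (−0.78 to −0.45) from the ninth to the last 10% of the gene, but it fell along the whole gene, which can hide a small rise. Base composition at gene ends, unannotated starts and neighbouring genes under 1 kb stay open too.

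H2AZ peaks found with only 1 of the antibodies were mostly weak. The calling threshold as a cause stays open: 0.0230% (0.0047 to 0.0672) of H2AZ CST peaks in the highest quartile were missing from the H2AZ Abcam list, which restates the pattern and does not test it. A difference in the kind of site cannot be told apart from a difference in peak strength. Among own peaks of the lowest quartile H3.3 overlapped 29.6% for Abcam and 23.7% for CST, a difference of 5.91 points (4.07 to 7.64), but the Abcam quartile reached a −log10 q of 8.0 and the CST quartile 6.40, and median widths were 203 and 187 bp. A difference between the antibodies in what they bind and a difference in depth between their libraries stay open.

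Peaks on unplaced or unlocalised sequences were flagged because they lie outside the chromosomes compared: there were 11 for H2AZ CST, 11 for H2AZ Abcam, 27 for H3.3, 22 for H4K16ac and 5 for H3K79me2. The antibodies to H2AZ were flagged for a difference in their overlap with H3K79me2, where the log2 ratio of Abcam exceeded that of CST by 0.055 (0.029 to 0.084), while the intervals for H3.3 (0.019) and H4K16ac (0.024) reached 0.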

How the results depend on the processing

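The settings added after seeing the data were gene-end peaks placed at other gene ends, the distal 3 Mb left out, peaks near featureless stretches left out and no minimum gene length. All 10 pair overlaps, the 5 enrichments at gene ends, the 6 odds ratios and the excess of H4K16ac over H3K79me2 at H3.3 peaks kept their direction and their call under every setting that applied to them. Their sizes did not stay fixed: the overlap of H3.3 with H4K16ac lay between 2.27 with peaks moved by 100 kb to 1 Mb and 4.86 with summit overlap.

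The comparisons of H3.3 with H2AZ CST did not hold in that way. For H4K16ac peaks the log2 difference of 0.18 became 0.010 with the 10000 strongest peaks of each list, −0.047 with peaks joined within 1 kb and −0.41 with peaks moved by 100 kb to 1 Mb, and rose to 0.71 with gene-end peaks placed at other gene ends. For H3K79me2 peaks the difference near 0 became −0.19 with the 10000 strongest peaks, −0.23 with summit overlap and −0.33 with moved peaks. It was 0.33 with gene-end peaks placed at other gene ends and 0.017 with the distal 3 Mb left out. The cause was not tested.

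Shares of genes with a peak at an end moved by more than counting error, as fewer peaks, other windows or other genes are counted. In the order H2AZ CST, H2AZ Abcam, H3.3, H4K16ac and H3K79me2 they were 37.4%, 39.4%, 28.3%, 16.3% and 43.4% with the 10000 strongest peaks, and 43.9%, 44.1%, 39.9%, 35.0% and 32.4% over all annotated genes. They were 67.4%, 68.7%, 60.3%, 48.9% and 52.6% with windows of 500 bp, and 73.7%, 73.7%, 67.1%, 59.0% and 57.2% with windows of 2 kb. With −log10 q of at least 5 H2AZ CST had 69.5%, H3.3 63.1% and H4K16ac 49.8%. Without the distal 3 Mb H3.3 had 63.3% and H4K16ac 53.1%. Joining peaks within 1 kb left 38481 H3.3, 42379 H4K16ac and 22531 H3K79me2 peaks, and cannot change whether a gene end is marked.

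Of 303 shares of gene lists and numbers of signals at named genes, 215 were lower with the 10000 strongest peaks, 6 were lower with −log10 q of at least 5, 23 were lower with windows of 500 bp and 20 were higher with windows of 2 kb. With no minimum gene length 1 of 130 was lower. The planned setting on peaks near runs of N was not run, because no genome sequence was used here. No paired analysis was possible because each antibody had 1 library. Read depth is not given in the sources used here, so the lack of a peak does not show the lack of a mark.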

Other observations

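H3K79me2, the mark that DOT1L writes, covered DOT1L and MLLT1 over 67.3% and 48.9%. No list of elongation regulators was tested. The median splicing and translation factor genes were covered over 64.8% and 45.0%. MLLT1, a subunit of elongation complexes, also carried H3.3 over 22.5% and H4K16ac over 30.1%. Near the end of chromosome 17, CD7 was covered over 100% by H3.3 and 86.7% by H4K16ac. Near the end of chromosome 16, the replication licensing gene CDT1 was covered over 94.5% and 55.3%. CDT1 also had H3K79me2 over 98.0%, and CD7 had none.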
